A study of Mus musculus with 2 samples.

How the data were processed

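The series measured H3K4me3 by ChIP-seq in hindbrain of newborn (postnatal day 0) mice, per the labels, in 2 samples, replicate 1 and replicate 2, which carry separate biosample labels and the same donor label. Both are pools of males and females of the same strain, replicate 1 from 15 mice and replicate 2 from a number not given, and the labels give a library size range of 300 to 500 bp. The 4 peak lists used were those of replicate 1, of replicate 2, of the pooled replicates and of replicated peaks. Per the deposited notes, the authors called peaks on mm10 against control alignments, made the pooled list from both replicates and derived the replicated list from both replicate lists and the pooled list. The aligner, the peak caller and its thresholds are not given in the sources used here.

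The fold enrichment of each peak over control is the value the authors deposited in the signal column of their lists, and it was used within a list only. The −log10 q of each peak is also the value the authors deposited, in the q-value column, and served as a stricter threshold. The lists hold no read counts, so the depth per sample is not known from them. What they show of precision is the number of peaks and their −log10 q, with medians of 40.9 in replicate 1, 40.3 in replicate 2, 90.8 in the pooled list and 154 in the replicated list.

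Peaks were read with 1-based starts and kept on the 21 chromosomes. Peaks on unplaced scaffolds (22, 29, 31 and 18 in the 4 lists) were left out of the comparisons because they belong to no chromosome, and the alignments and signal tracks were not used here. No peak ran past a chromosome end of the genome, GRCm38 patch 6, whose coordinates are those of mm10. Gene starts came from GENCODE mouse release 21, with 21938 protein-coding genes. A gene counted as marked when a peak overlapped the 1000 bp on either side of any of its transcript starts. Peaks at most 1000 bp apart were merged into domains, and the widest domain at a gene's starts gave its width. The CpG ratio of a gene is the highest observed/expected CpG value over its start windows. CpG islands were computed from the sequence with a length of at least 200 bp, GC of at least 50% and a CpG ratio of at least 0.6, and in a stricter form with 500 bp, 55% and 0.65.

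The tests, the 25 gene lists and the alternatives were fixed before the data were examined. Marked shares were tested by Fisher's exact test against other protein-coding genes, and shares in the broadest 5% of domains at starts by Fisher's exact test against other marked genes, each with Benjamini-Hochberg adjustment over the 25 lists. Median domain widths were tested by permutation with 100000 resamples, with adjustment over the 19 lists with at least 5 marked members. The smallest p this can give is 2e-05. All tests took both tails, and the threshold on adjusted p was 0.05. Marked shares were also ranked among 10000 random lists matched on deciles of CpG ratio, with ties counted at their midpoint. Chance overlap came from 100 circular shifts within chromosomes. Genes marked in 1 replicate only were compared by an exact binomial test. Spreads are SD over the 2 replicates, which were treated as separate pools because their biosample labels differ. They share a donor label, and whether they share any animals is not known from the labels. Wilson intervals cover counting error only. With 1 group there was no test between groups.

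The lists took in housekeeping genes, Hox groups 1 to 4, 5 to 8 and 9 to 13, hindbrain regional, cerebellar and telencephalic genes, and neuronal, transmitter, progenitor, glial, vascular, meningeal, choroid and ependymal genes. They also took in microglial, erythroid, liver, muscle, pluripotency and germline, imprinted, immediate early and sex chromosome genes. Lmx1b and Phox2b stood in 2 lists each. Of the 326 members, 4 are noncoding and were described but not tested. Genes were named by a rule fixed before the data were examined. It took up to 4 marked members of each list (the 2 widest and 2 narrowest domains), up to 4 unmarked members, and all members of the Hox lists and of the rarer side where it had at most 5. It also took the 20 genes with the widest domains, the 10 strongest peaks, the 10 strongest over 1000 bp from any start, and the 5 strongest genes found in each replicate only.

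Alternatives were tried for the window (500 and 2500 bp), the starts used (outermost only), the peak list (pooled, or −log10 q of at least 10, or each replicate alone), the merge distance (0 and 3000 bp), the share called broadest (10%), the background (genes with a CpG ratio of at least 0.6), the overlap needed (50% of 1 or both peaks), equal numbers of top peaks (20368 each) and the island definition. The steps were tested on simulated data. For replicate overlap, 80.3% of 22965 peaks were kept in a simulated copy and 80.3% recovered. The kept peaks were moved only slightly and recovery was counted among them alone, so that match was fixed beforehand and checks the code only. By a plain loop and by the function, 32 of 736 chromosome 19 peaks overlapped a shifted copy. For marked genes, 3000 of 3000 seeded genes were recovered among 21938. For the marked share, 1% of null lists of 15 genes and 86.5% of lists drawn with odds of 10 passed p 0.05, over 21938 genes. For domain width, 3.5% of null lists of 15 genes and 100% of those widened 2 or 3 times passed, over 14497 genes. For genes marked in 1 replicate only, 200 of 200 and 100 of 100 removed genes were recovered among 21938. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.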

Results

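H3K4me3, the histone H3 lysine 4 trimethylation that sits on nucleosomes at gene starts, was mapped by ChIP-seq in the hindbrain of newborn mice. The hindbrain is the part of the brain that gives rise to the cerebellum, pons and medulla. There was 1 group with 2 biological replicates, each a pool of males and females, and the labels give 15 mice for replicate 1. Each replicate had its own peak list, and the authors also deposited a pooled list and a list of replicated peaks. On the 21 chromosomes the lists held 27763 peaks in replicate 1, 27158 in replicate 2, 26209 in the pooled list and 22965 in the replicated list. The replicates averaged 27461 ± 428 peaks (SD, n = 2), which covered 37.6 ± 0.189 Mb. Peak lists carry no read totals, so the sequencing depth behind them is unknown. With 1 group, the comparisons were between gene groups within the replicated list and between the replicates.

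The mark lay mostly at gene starts. Of the 22965 replicated peaks, 15028 (65.4%) lay within 1000 bp of a protein-coding transcript start and 1210 (5.27%) at the start of another gene. A further 1097 (4.78%) overlapped exons, 2491 (10.8%) introns and 3139 (13.7%) lay between genes. The peaks at protein-coding starts were wide, with a median of 1976 bp against 539 bp in introns and 649 bp between genes, and they held 83.2% of the covered bases. Peaks moved round each chromosome by a random distance fell at protein-coding starts in 6.59% of cases on average and 7.39% at most over 100 shifts. In the replicates' own lists the share at protein-coding starts was 58.8% ± 0.45 (SD, n = 2), below that of the replicated list by more than this spread. The summits of peaks at starts lay a median of 147 bp downstream of the nearest start (quartiles 37 and 239 bp), and 80.7% lay on the downstream side.

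Most of these sites were CpG-rich. A CpG island computed from the mm10 sequence overlapped 83.9% of replicated peaks, 94.0% of those at protein-coding starts and 64.8% of the others, against 12.1% of shifted peaks. With a stricter island definition the shares were 62.2%, 82.0% and 24.8%, against 2.31% of shifted peaks. The island share was 73.6% in replicate 1 and 75.1% in replicate 2.

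A total of 14497 of the 21938 protein-coding genes (66.1%) were marked, meaning that a replicated peak overlapped the 1000 bp on either side of an annotated start. The replicates' own lists marked 14586 and 14533 genes, or 66.4% ± 0.171 (SD, n = 2). Marking followed CpG content closely. Of the 8442 genes with a CpG observed/expected ratio of at least 0.6 at a start, 99.1% were marked, and of the other 13496 genes 45.4% were marked. Whether the mark set apart gene groups was therefore read in 3 ways over 25 gene lists fixed before the data were examined. These were the share of members marked, that share among 10000 random lists matched on CpG ratio, and the width of the domain at the start. A domain joined peaks at most 1000 bp apart.

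Regional and neuronal genes were marked almost without exception. All 18 hindbrain regional factors were marked, as were 17 of 18 cerebellar lineage genes, all 15 pan-neuronal genes and all 15 neural progenitor genes. All 18 telencephalic factors, which pattern the forebrain, were marked too. The exception was Pcp2, a Purkinje cell gene with a CpG ratio of 0.186 at its start. All 18 housekeeping genes, all 12 Hox genes of groups 1 to 4, all 11 of groups 5 to 8, all 10 immediate early genes and 15 of 16 imprinted genes were marked. Against 66.1% of other genes, these 10 lists had higher shares by Fisher's exact test, with adjusted p from 0.00314 to 0.0364, in both replicates' own lists except for the immediate early genes (adjusted p 0.058 in replicate 1). Only the pan-neuronal list stood at the upper end of the CpG-matched lists, at percentile 99.8, where matched lists averaged 79.1%. The other 9 stood between percentiles 58.3 and 93.0, and among genes with a CpG ratio of at least 0.6, where 99.1% were marked, a higher share could not be tested. Calls were lost with the outermost start only for Hox 1 to 4, Hox 5 to 8, telencephalic and imprinted genes (adjusted p 0.0534 to 0.549, Fisher's exact test). They were lost with −log10 q of at least 10 for Hox 1 to 4, Hox 5 to 8 and hindbrain genes (0.0863 to 0.325), and in the pooled list for imprinted (0.0528) and immediate early genes (0.0543), the latter also with a 2500 bp window (0.0706).

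**Figure D1:**
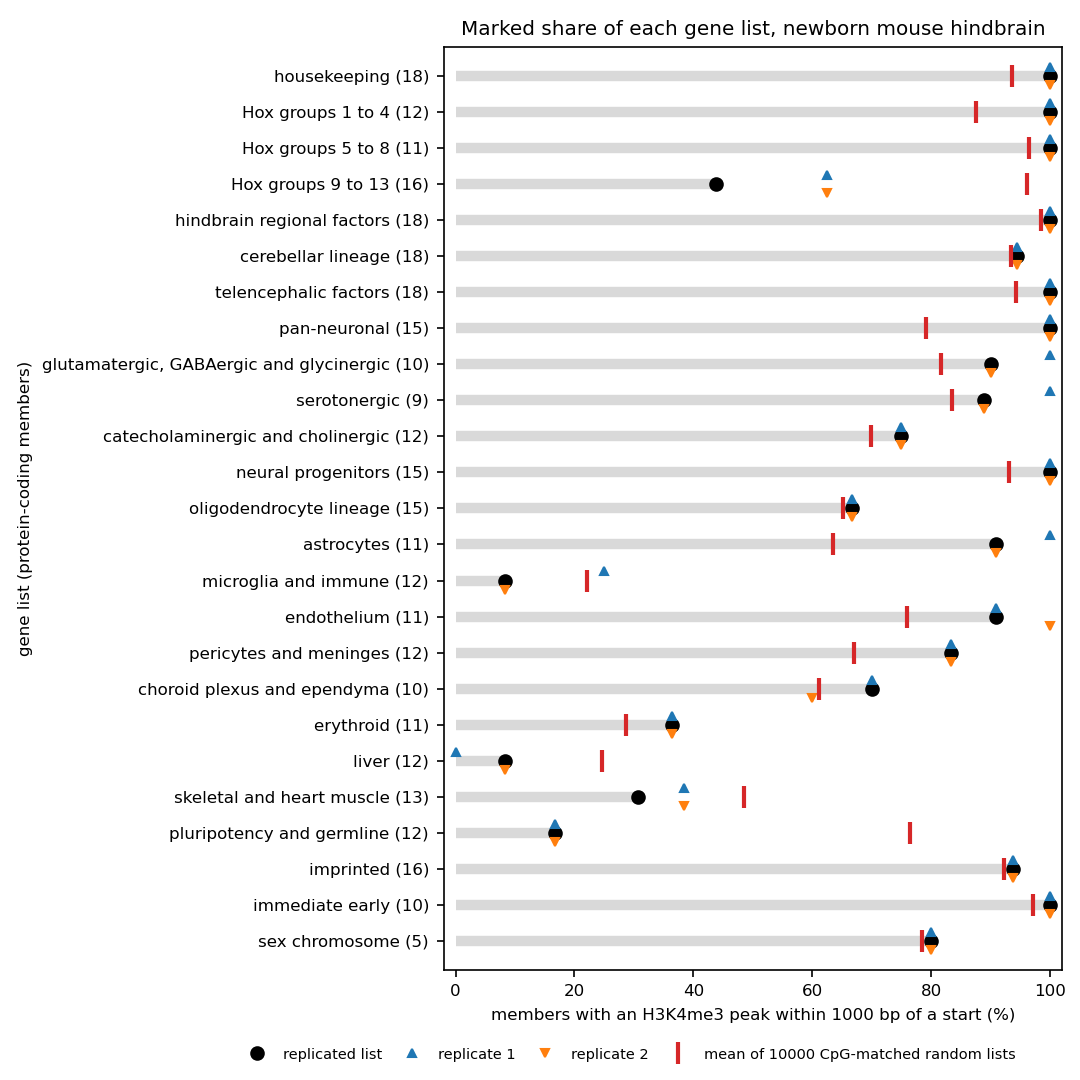
Share of members with an H3K4me3 peak within 1000 bp of a start (%, horizontal axis) for each of the 25 gene lists (vertical axis, with the number of protein-coding members). Black circles show the replicated list, triangles the 2 replicates and red ticks the mean of 10000 random lists matched on CpG ratio; the pluripotency and germline list (16.7%) and Hox groups 9 to 13 (43.8%) lie far to the left of their matched lists (76.4% and 96.2%).

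Transmitter and glial groups were marked in part. Of 10 glutamatergic, GABAergic and glycinergic genes 9 were marked, with Slc17a8, a vesicular glutamate transporter, peaked in replicate 1 only. Of 9 serotonergic genes 8 were marked, and Tph2, which encodes the neuronal enzyme of serotonin synthesis, had a peak in replicate 1 only. Of 12 catecholaminergic and cholinergic genes 9 were marked. Th, Dbh and Pnmt, which encode enzymes of catecholamine synthesis, had no start peak in the replicated list or either replicate's own list. Ddc, which encodes another such enzyme, was marked by a domain of 368 bp (294 and 421 bp in the replicates). That domain (chromosome 11, 11821740 to 11822107) lay at an internal annotated start, far from the gene's outermost start at 11898144, with an enrichment of 3.63. Of 11 astrocyte genes 10 were marked, and Gfap, an intermediate filament gene, had a peak of 565 bp in replicate 1 only. Of 15 oligodendrocyte lineage genes 10 were marked. The 5 unmarked ones, Mag, Mobp, Mog, Opalin and Plp1, had no start peak in either replicate. Their CpG ratios ran from 0.1855 at Mog to 0.256 at Mobp, and the list stood at percentile 58.25 of CpG-matched lists. The marked members took in Cnp (2118 bp) and Myrf (919 bp). The shares of these lists did not pass Fisher's exact test against other genes (adjusted p from 0.156 to 1), except that the astrocyte share was higher in replicate 1's own list (0.0391) and in the pooled list (0.0392). The astrocyte list stood at percentile 99.9 of CpG-matched lists, which averaged 63.4%.

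Of the genes of other cell types and organs, vascular and meningeal genes were mostly marked, with 10 of 11 endothelial genes and 10 of 12 pericyte and meningeal genes. Tie1, an endothelial receptor gene, and Dcn and Lum, which encode matrix proteoglycans, were the unmarked ones. Of 10 choroid plexus and ependymal genes 7 were marked, without Ttr, Folr1 and Kcne2. In the erythroid list 4 of 11 were marked (Epor, Klf1, Gypa and Nfe2), and the globin genes Hba-a1 and Hba-a2 were not. No share among these 4 lists passed Fisher's exact test against other genes (adjusted p from 0.0881 to 1), but the endothelial share was higher in replicate 2's own list (0.0363) and the erythroid share lower with a 500 bp window (0.0256). The pericyte and meningeal list stood at percentile 98.8 of CpG-matched lists. In the microglial and immune list 1 of 12 genes was marked, Tmem119, by a domain of 285 bp that was called in replicate 2 (230 bp) and not in replicate 1. Replicate 1's own list marked 3 of the 12, C1qa among them, and replicate 2's 1. In the liver list 1 of 12 was marked, Apoa1, whose 1374 bp domain was called in replicate 2 but not at its start in replicate 1, where none of the 12 was marked. That domain (chromosome 9, 46229710 to 46231083) lay at an internal annotated start, over 1000 bp downstream of the outermost start at 46228580. It ran past the gene's end at 46230466. In the muscle list 4 of 13 (Ckm, Des, Myod1 and Tnni3) and in the pluripotency and germline list 2 of 12 (Dazl and Dppa3) were marked. The Ckm domain was shared with Klc3 and ended before the Ckm gene began. Its enrichment was 22.4, against 4.75 to 5.25 at Des, Myod1 and Tnni3. The microglial, liver, muscle, and pluripotency and germline shares were lower than the 66.1% of other genes by Fisher's exact test, with adjusted p of 0.000703, 0.000703, 0.0331 and 0.00314. In each replicate's own list 5 of 13 muscle genes were marked, and the muscle call was lost (adjusted p 0.0598 in replicate 1 and 0.070 in replicate 2, Fisher's exact test), as it was with a 2500 bp window (0.204). Set against CpG-matched lists, the microglial, liver and muscle shares stood at percentiles 9.53, 4.79 and 3.22, while no matched list fell as low as the pluripotency and germline list, where matched lists averaged 76.4%.

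Hox genes encode homeodomain factors that pattern the body axis, with low group numbers expressed furthest forward. All 12 genes of groups 1 to 4 and all 11 of groups 5 to 8 were marked, and 7 of 16 in groups 9 to 13. Hoxa1 and Hoxa2 shared a domain of 14.3 kb (chromosome 6, 52156621 to 52170946), Hoxd3 and Hoxd4 one of 14.1 kb (chromosome 2, 74726742 to 74740839), and Hoxb3 lay in one of 11.8 kb. In replicate 2 Hoxb3 and Hoxb4 shared 1 domain of 17.0 kb. Hoxb5 and Hoxb6 shared 12.7 kb (15.1 and 7.88 kb in the replicates), and Hoxb7 and Hoxb8 5.24 kb. At the other end of the range, Hoxa3 had 499 bp (1407 and 1997 bp in the replicates' own lists) and Hoxb1 513 bp (1329 and 380 bp). The Hoxa3 domain lay at its outermost starts and was shared with Gm28308. A replicated peak within the Hoxa3 gene (chromosome 6, 52172113 to 52180854, enrichment 14.9) lay outside its start windows. The short width thus does not describe the whole gene. The remaining members of groups 1 to 4 lay between 1595 bp at Hoxd1 and 3846 bp at Hoxb2, with Hoxc4 at 2734 bp, Hoxa4 at 3050 bp and Hoxb4 at 3557 bp (3405 bp in replicate 1). In groups 5 to 8, Hoxa5 had 3079 bp, Hoxc5 2294 bp, Hoxc6 2081 bp, Hoxa6 1534 bp, Hoxd8 1343 bp, Hoxa7 985 bp and Hoxc8 593 bp. The marked genes of groups 9 to 13 (Hoxb9, Hoxd9, Hoxd11, Hoxa13, Hoxd13, Hoxa11 and Hoxc13) lay in domains of 503 to 1749 bp. Several other Hox widths differed between the lists, such as Hoxc13 (503 bp, with 1820 and 230 bp in the replicates), Hoxd9 (1410 bp, with 1061 and 2589 bp), Hoxc6 (1243 bp in replicate 2) and Hoxa6 (938 bp in replicate 1). Hoxb13, Hoxc11, Hoxc12, Hoxd10 and Hoxd12 had no start peak in the replicated list or either replicate's own list. Hoxa10 and Hoxc9 had short ones in both replicates, Hoxa9 in replicate 2 and Hoxc10 in replicate 1. The marked share of groups 9 to 13 did not differ from that of other genes by Fisher's exact test (adjusted p 0.106), and each replicate's own list marked 10 of the 16. No CpG-matched list had so low a share, and matched lists averaged 96.2%. Among genes with a CpG ratio of at least 0.6 the share was lower (adjusted p 1.22e-08, Fisher's exact test).

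**Figure D2:**
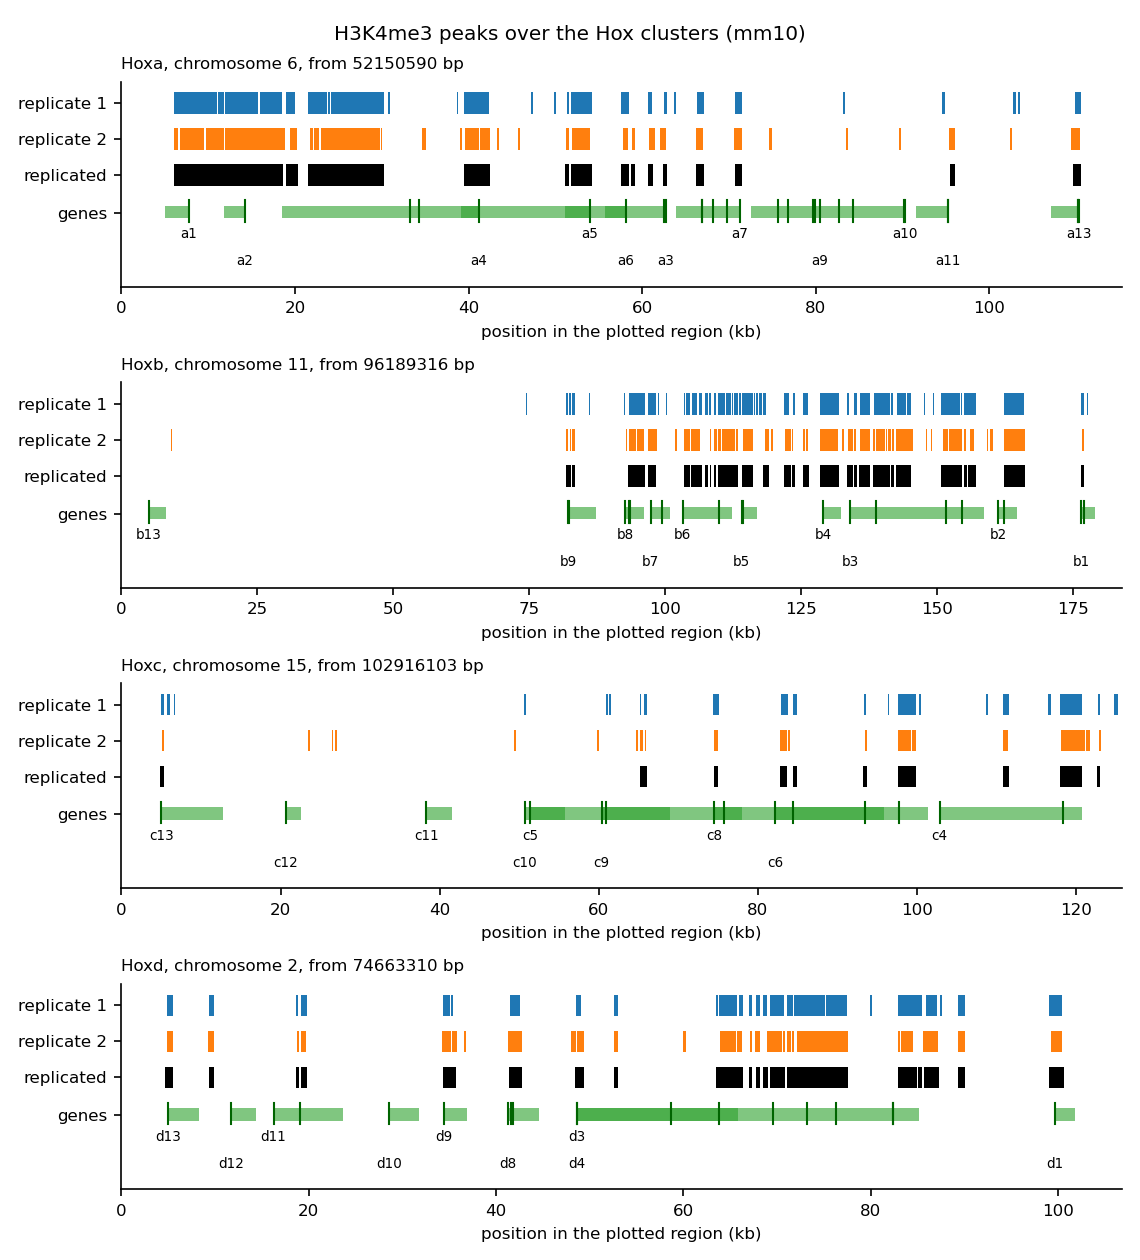
Peaks of replicate 1 (blue), replicate 2 (orange) and the replicated list (black) over the 4 Hox clusters on mm10, with position in the plotted region in kb on the horizontal axis. Green bars span all annotated transcripts of each Hox gene and dark ticks mark their starts, with the gene's letter and number at its outermost start; wide runs of peaks cover Hoxa1 and Hoxa2 (14.3 kb) and Hoxd3 and Hoxd4 (14.1 kb), and short or no replicated peaks lie at the starts of groups 9 to 13.

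Domain widths at marked genes differed between gene groups. The median domain at a marked gene was 2193 bp (quartiles 1632 and 2977 bp). The 9 marked glutamatergic, GABAergic and glycinergic genes had a median of 8586 bp, the 17 cerebellar genes 7920 bp, the 18 hindbrain regional factors 6964 bp, the 15 pan-neuronal genes 4898 bp and the 15 neural progenitor genes 4368 bp. All 5 were wider than other marked genes by permutation test (adjusted p 0.000152 for the progenitors and 9.5e-05, from the smallest p that the permutations can give, for the other 4). In the replicates the cerebellar medians were 8656 and 7867 bp and the hindbrain regional medians 6837 and 6474 bp, and each of the 5 lists was wider in both. The transmitter median was 4625 bp in replicate 1 and 8423 bp in replicate 2. Its excess over other genes, 6393 bp, was 1600 to 3705 bp with −log10 q of at least 10, with only touching peaks merged, in the pooled list, in replicate 1 and with the outermost start only, and it passed under each (adjusted p at most 0.00652, permutation test). Wider domains were also found by permutation test at the immediate early genes (4063 bp, adjusted p 0.00179), Hox groups 1 to 4 (3702 bp, 0.00304), imprinted genes (3644 bp, 0.00242), astrocyte genes (3563 bp, 0.0112) and housekeeping genes (3140 bp, 0.0112). The Hox 1 to 4 median was 3730 bp in replicate 1 and 9025.5 bp in replicate 2. Its excess of 1508.5 bp rose to 6798.5 bp in the pooled list and 7396.5 bp with merging up to 3000 bp. Restricting each gene to its outermost start ended the call for Hox groups 1 to 4 (adjusted p 0.0785) and imprinted genes (0.129). The 7 marked genes of Hox groups 9 to 13 were narrower, with a median of 948 bp (adjusted p 0.00179, permutation test).

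Telencephalic factors, though all marked, had a median of 2760 bp that did not differ from other marked genes by permutation test (adjusted p 0.109). That rested on the setting, since the telencephalic median was wider by permutation test in replicate 1's own list (adjusted p 0.0458), in the pooled list (0.00486) and with peaks merged up to 3000 bp (0.00114). In replicate 2's own list, at 2492 bp, it was not (0.280). The oligodendrocyte (3074 bp, 0.0776), endothelial (1785 bp, 0.243), choroid and ependymal (1611 bp, 0.169), pericyte and meningeal (2228 bp, 0.942), serotonergic (2048 bp, 0.752), catecholaminergic and cholinergic (1927 bp, 0.539) and Hox 5 to 8 (2294 bp, 0.825) lists did not pass the test either. Oligodendrocyte genes were wider in replicate 1 (adjusted p 0.0311, permutation test), in the pooled list (0.0498) and with merging up to 3000 bp (0.0192), and serotonergic genes with that merging (0.0089). Catecholaminergic and cholinergic genes were narrower in replicate 2 (adjusted p 0.025, permutation test), with −log10 q of at least 10 (0.0346) and with only touching peaks merged (0.00537). Members ranged widely within a list. The hindbrain regional factors ran from Evx1 (1455 bp, with 564 bp in replicate 2) and Pax8 (2823 bp) to Meis1 (14.8 kb) and Meis2 (20.0 kb), and the cerebellar genes from Calb1 (2083 bp), a calcium-binding protein of Purkinje cells, and Rora (3523 bp) to Zic1 and Zic4. In the transmitter list Slc6a9 and Slc17a7 had 2252 and 2849 bp, while Slc32a1, the vesicular transporter for GABA and glycine, and Gad1, which encodes an enzyme of GABA synthesis, had 10.8 and 11.3 kb. The widest telencephalic domains were those of Bcl11b (8820 bp) and Neurod6 (5193 bp, with 2973 and 3021 bp in the replicates), and the narrowest those of Gsx2 (1102 bp) and Dlx5 (1274 bp). The progenitor genes ran from Neurog1 (1151 bp) and Prom1 (2054 bp) to Sox2 (10.7 kb) and Pax3 (11.4 kb). In the serotonergic list Gata3 (11.1 kb, with 6977 bp in replicate 1) and Lmx1b (8200 bp, with 5266 bp in replicate 2) stood against Maob (650 bp) and Slc18a2 (1007 bp). Olig2 (10.5 kb) and Pdgfra (7416 bp) led the oligodendrocyte list and Otx2 (13.4 kb) the choroid and ependymal list.

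**Figure D3:**
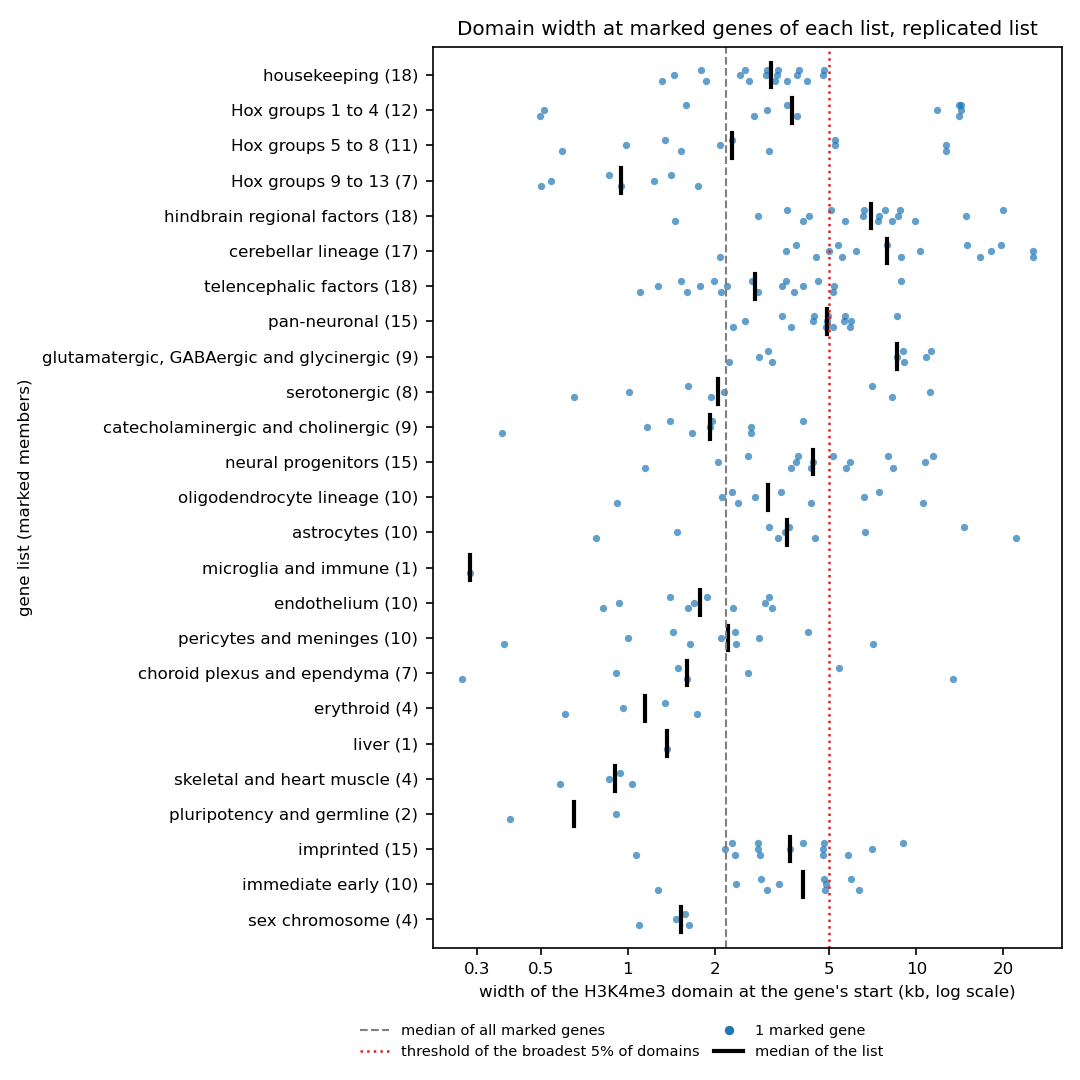
Width of the H3K4me3 domain at the start of each marked gene (kb, horizontal log axis) by gene list (vertical axis, with the number of marked members), from the replicated list. Blue points are genes, black bars are list medians, the dashed line is the median of all marked genes (2193 bp) and the dotted line the threshold of the broadest 5% of domains (4996 bp); the medians of the hindbrain regional (6964 bp), cerebellar (7920 bp) and transmitter (8586 bp) lists lie beyond the dotted line and that of the telencephalic list (2760 bp) does not.

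The broadest 5% of domains at starts, those of at least 4996 bp, held 728 genes. They took in 13 of the 18 hindbrain regional factors (adjusted p 1.98e-12, Fisher's exact test), 12 of the 17 cerebellar genes (1.44e-11), 7 of the 15 progenitor genes (2.95e-05), 5 of the 9 transmitter genes (0.00021), 6 of the 15 pan-neuronal genes (0.000266) and 5 of the 12 genes of Hox groups 1 to 4 (0.000774). The 5 Hox genes lay in 3 domains, those of Hoxa1 with Hoxa2, Hoxd3 with Hoxd4, and Hoxb3, and their call was lost with the outermost start only (0.0524) and with only touching peaks merged (0.0579). The pan-neuronal call was lost with merging up to 3000 bp (0.414). In Hox groups 5 to 8, 4 of 11 genes lay there (0.0056), all in the pair of shared Hoxb domains, and with only touching peaks merged none did. That call was also lost with −log10 q of at least 10 (0.175) and with merging up to 3000 bp (0.273). The serotonergic list had 3 of 8 (0.0183) and the oligodendrocyte and astrocyte lists 3 of 10 each (0.029); these calls were lost with only the outermost start of each gene (0.125, 0.16 and 0.125), and the serotonergic and oligodendrocyte ones with only touching peaks merged (0.637 and 0.706). The serotonergic call was lost with −log10 q of at least 10 (0.127) and with the broadest 10% (0.0836) too. Of the telencephalic factors 3 of 18 lay among the broadest (0.113; 0.0267 in the pooled list and 0.0481 with merging up to 3000 bp), of the imprinted genes 3 of 15 (0.083), of the choroid and ependymal genes 2 of 7 (0.0931), of the immediate early genes 2 of 10 (0.155) and of the housekeeping genes none. The imprinted list passed with merging up to 3000 bp (0.0303) and with the broadest 10% (0.00888). The immediate early list passed in replicate 2 (0.0261) and under 4 other settings (0.00745 to 0.0389), all by Fisher's exact test.

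The widest domain at a protein-coding start was the one shared by Zic1 and Zic4, zinc finger factors of cerebellar and dorsal neural development. It measured 25.4 kb (chromosome 9, 91348879 to 91374301), with 25.2 kb in replicate 1 and 35.4 kb in replicate 2. Next came Nr2f2 (22.6 kb), Nfib (22.1 kb), Ebf3 (20.0 kb), Meis2 (20.0 kb; chromosome 2, 116053870 to 116073864), Zic2 (19.6 kb), Pax6 (18.1 kb) and Lhx5 (16.6 kb). Pou3f2 (15.4 kb), Qk (15.1 kb), Pou3f3 (15.1 kb), Lhx1 (14.9 kb), Meis1 (14.8 kb) and Nfia with E130114P18Rik (14.7 kb) followed. Hoxa1 and Hoxa2, and Gm28230 and Hoxd3 of the Hoxd3 domain, completed the 20 genes. Hoxd4 lay in that same domain and was left out because ties were taken by name. Of these 20 genes, Qk encodes an RNA-binding protein, E130114P18Rik and Gm28230 have no assigned function here, and the others encode DNA-binding transcription factors. Ebf3 was narrower in replicate 2, at 14.4 kb.

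**Figure D4:**
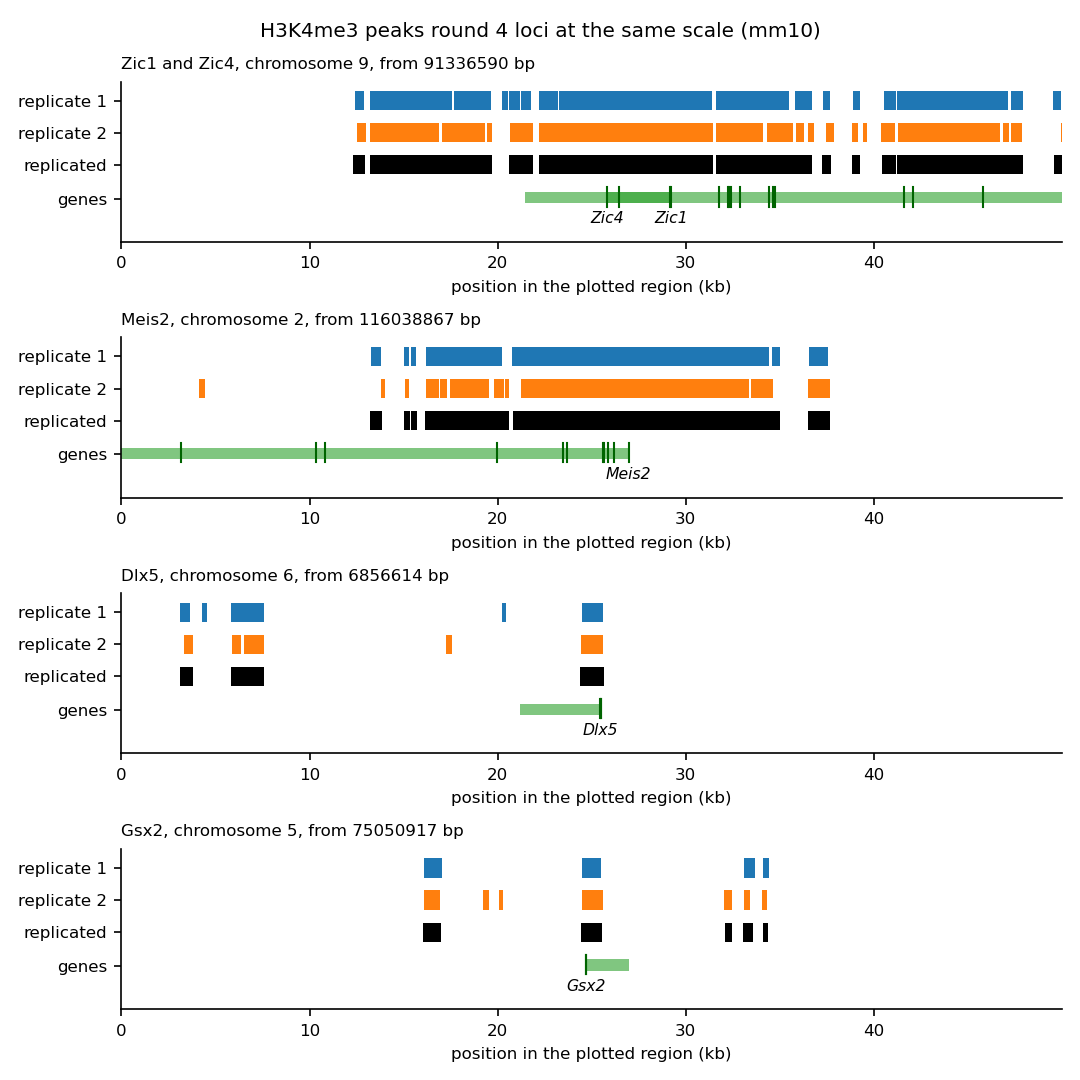
Peaks of replicate 1 (blue), replicate 2 (orange) and the replicated list (black) in windows of the same length on mm10 round the widest cerebellar (Zic1 and Zic4) and hindbrain regional (Meis2) members and the 2 narrowest telencephalic ones (Dlx5 and Gsx2), with position in kb on the horizontal axis. Green bars are the annotated genes, clipped at the window's edge, and dark ticks their starts; domains span 25.4 kb at Zic1 and Zic4 and 20.0 kb at Meis2, and 1274 and 1102 bp at Dlx5 and Gsx2, against a telencephalic median of 2760 bp.

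Among the remaining lists, the imprinted genes ranged from Dlk1 (1066 bp, with 2484 bp in replicate 1) and Plagl1 (2176 bp) to Peg3 (7033 bp) and Gnas (8968 bp). Ndn had no start peak in the replicated list or either replicate's own list. The noncoding Meg3 lay in a domain of 4794 bp (chromosome 12, 109539233 to 109544026), and H19 was marked in both replicates' lists but not in the replicated list. The immediate early genes ran from Arc (1273 bp) to Egr3 (6328 bp). Of the Y-linked genes, Kdm5d, Ddx3y, Uty and Eif2s3y were marked by domains of 1096 to 1629 bp and Sry, the testis-determining gene, was not, a share that did not differ from other genes (4 of 5, adjusted p 0.759, Fisher's exact test). The 4 marked genes carried the 4 replicated peaks of the Y chromosome. The noncoding Xist start lay in a domain of 3465 bp (chromosome X, 103480448 to 103483912) and Tsix had one of 1121 bp, in pools that held both sexes.

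The strongest peaks by enrichment lay at gene starts. Enrichments here are the values the authors deposited for each peak, read within a list only. The top 10 of the replicated list had enrichments of 59.3 to 62.2. They lay at the starts of Clptm1, Tpp2, Dpm1, Wdr43, Cops2, Ythdf1, Hsp90ab1, Zc3h13 and Kmt2d and of the noncoding 1810026B05Rik, 16022 bp from Chd2. All 10 overlapped a CpG island and a peak in both replicates. Their widths, 1812 to 5592 bp, were far from those of the widest domains. The 10 strongest peaks over 1000 bp from any annotated start had enrichments of 40.3 to 47.2. They lay in a coding exon of Sf3b5, in introns of Lncppara, Nup160 and Kdm6b, and between genes 2932 bp from the start of Mos and 13541 bp from that of Gpr161. The other 4 lay between genes on chromosomes 3, 9, 17 and 18, with the nearest protein-coding starts (Hfe2, Arhgap32, Zfp947 and Dtna) 24450 to 104805 bp away. All 10 overlapped a CpG island, under the stricter definition too, and a peak of each replicate. The peak in Lncppara was 13161 bp wide (chromosome 15, 85668876 to 85682036).

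Peaks found in 1 replicate only were narrow and weak. A peak of the other replicate overlapped 86.4% of replicate 1 peaks and 87.4% of replicate 2 peaks, and the covered bases had a Jaccard index of 83.6%. Circular shifts gave 2.75% and 2.79% on average and 3.27% at most. The 3779 replicate 1 peaks without a partner had a median width of 251 bp and enrichment of 2.81, against 1329 bp and 16.3 for those with one. In replicate 2 the 3426 peaks without a partner had 260 bp and 3.24, against 1366 bp and 18.6. Across 22342 paired peaks, which are not independent replicates, the enrichments of the replicates had a Spearman correlation of 0.969 and the widths one of 0.966.

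At the level of genes, 14436 were marked in both replicates, or 98.3% of those marked in either. Replicate 1 alone marked 150 and replicate 2 alone 97, an unequal split (p = 0.0009, exact binomial test, both tails). The test compares 2 peak lists, each from 1 pool of animals. With only peaks of −log10 q of at least 10 the counts were 100 and 78 (exact binomial p 0.115), and with equal numbers of top peaks 106 and 103 (0.890). The strongest of these genes were Gpsm3, Foxh1, Cby3, Car15 and Tsks in replicate 1 and Rnf151, Tnnc1, B3gnt4, Tchh and Adam8 in replicate 2. Gpsm3, Foxh1, Car15, Rnf151, Tnnc1 and Adam8 shared their domain with the start of a neighbouring gene, such as Pbx2 for Gpsm3 and Rps2 for Rnf151.

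The replicated list was a subset of the pooled list, peak for peak. It kept 22965 of the 26209 pooled peaks (87.6%, 95% Wilson interval 87.2 to 88.0), all with the same coordinates. Of the kept peaks 21939 (95.5%) overlapped a peak of both replicates, 578 of replicate 1 only, 427 of replicate 2 only and 21 of neither. The 3244 peaks left out had a median width of 272 bp and enrichment of 2.63, against 1502 bp and 20.0 for those kept, and 55 of them overlapped both replicates.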

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

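Peaks on unplaced scaffolds, which no comparison used, were flagged as a signal in data outside the main measurement. There were 22 in replicate 1, 29 in replicate 2, 31 in the pooled list and 18 in the replicated list, against the limit of 3 that a count of 0 allows. Their median enrichments were 3.03, 3.31, 2.58 and 4.00, and they made up at most 0.118% of a list. No explanation of them was tested.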

How the results depend on the processing

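Of 700 values under alternatives, 608 stayed the same, 40 were weaker, 24 stronger, 3 reversed and 25 moved. Hindbrain regional and cerebellar widths and shares in the broadest domains stayed past the threshold under all 9 and 10 alternatives (adjusted p 5.71e-05 to 0.000127 for width by permutation, at most 2.13e-09 and 1.35e-08 for the broadest by Fisher's exact test). The low shares of the microglial, liver and pluripotency and germline lists stayed past it under all 7, 7 and 8 (at most 0.0128, 0.00404 and 0.00404). The number of genes marked ranged from 13709 to 14713. The adjusted p-values below are from Fisher's exact tests for marked and broadest shares and permutation tests for widths. Except where said, the cause was not tested.

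The overlap of replicate 1 and replicate 2 peaks moved from 86.4% and 87.4% to 82.5% and 83.4% with 50% of the peak, to 75.4% and 77.1% with 50% of both, to 96.5% and 97.01% with −log10 q of at least 10 and to 94.3% and 93.8% with equal numbers of top peaks. The share at protein-coding starts moved from 65.4% to 63.8% and 70.7% with windows of 500 and 2500 bp, 59.7% in the pooled list, 75.8% with −log10 q of at least 10, and 58.5% to 59.1% with a replicate left out. The island share was 62.2% by the strict definition and 73.6% to 75.1% with a replicate left out. The replicate 1 share of genes marked in 1 replicate only fell from 60.7% to 56.2% (exact binomial p 0.115) with −log10 q of at least 10 and to 50.7% (0.890) with equal numbers of top peaks.

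Among genes with a CpG ratio of at least 0.6 only 73 are unmarked, so a higher share could not pass, and adjusted p of 1 says nothing about housekeeping, Hox 1 to 4, Hox 5 to 8, hindbrain, cerebellar, telencephalic, pan-neuronal, progenitor, imprinted and immediate early shares. Muscle has 1 gene there, Des, which is marked, so its reversal (1) is no test. There 0 lists passed as higher and 2 as lower, pluripotency and germline and Hox 9 to 13, while the microglial and liver lists have no gene there and were not tested. With the outermost start only, marked shares were lost for Hox 1 to 4 (0.0741), Hox 5 to 8 (0.111), telencephalic (0.0534) and imprinted genes (0.549), leaving 6 lists higher. Widths were lost for Hox 1 to 4 (0.0785) and imprinted genes (0.129), and broadest shares for Hox 1 to 4 (0.0524), serotonergic (0.125), oligodendrocyte (0.16) and astrocyte genes (0.125), leaving 6. With −log10 q of at least 10, marked shares were lost for Hox 1 to 4 (0.325), Hox 5 to 8 (0.173) and hindbrain genes (0.0863), and broadest shares for Hox 5 to 8 (0.175) and serotonergic genes (0.127). With 2500 bp, the muscle (0.204) and immediate early (0.0706) marked shares were lost, and in the pooled list the imprinted (0.0528) and immediate early ones (0.0543). With a replicate left out, they ranged from 0.0598 to 0.070 for muscle and 0.0363 to 0.058 for immediate early genes. Narrower lists numbered 2 with 2500 bp, 2 with only touching peaks merged and 2 to 3 with a replicate left out, against 1.

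With only touching peaks merged, broadest shares were lost for Hox 1 to 4 (0.0579), serotonergic (0.637) and oligodendrocyte genes (0.706). The Hox 5 to 8 share, with no member left there, counted as reversed but was not past the threshold (1). With peaks merged up to 3000 bp, the serotonergic width became wider (0.0089) and counted as reversed. In the main setting it had made no call (−145 bp, adjusted p 0.752, permutation test). Broadest shares were lost with that merging for Hox 5 to 8 (0.273) and pan-neuronal genes (0.414). With the broadest 10%, the serotonergic share was lost (0.0836). The Hox 9 to 13 marked share, not past the threshold at 0.106, was lower with −log10 q of at least 10 (0.00845) and against CpG-rich genes (1.22e-08), and gave 0.9 in the pooled list and 0.827 to 0.862 with a replicate left out.

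No paired analysis was possible because there is 1 group. What depth limits was not measured, since read totals are unknown, and no list says whether a missing peak lay just below its threshold.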

Other observations

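Chemosensory receptor genes were almost free of the mark. Of 1135 odorant receptor genes 3 were marked (Olfr1033, Olfr658 and Olfr94), of 329 vomeronasal receptor genes 1 (Vmn1r4, adjusted p 1.4e-153) and of 35 bitter taste receptor genes 0 (9.87e-17), all by Fisher's exact test adjusted over 17 families. Of 57 keratin-associated protein genes 1 was marked (9.53e-25) and of 42 beta-defensin genes 0 (5.98e-20). The median CpG ratios of these families ran from 0.123 (vomeronasal receptors) to 0.169 (keratin-associated proteins). No CpG-matched lists were drawn for families, so the low shares were not separated from CpG content. Core machinery genes were mostly marked, with 76 of 79 ribosomal protein genes (2.12e-10), 38 of 40 proteasome genes (5.48e-05) and 45 of 46 complex I genes (3.44e-07). The unmarked ones were Rpl10l, Rpl39l and Rpl3l, Psma8 and Psmb11, and Ndufa4l2. Among the clustered protocadherins, 9 of 14 alpha, 14 of 22 beta and 19 of 21 gamma genes were marked, with short median domains of 567, 458 and 959 bp, and only the gamma share was higher than that of other genes (0.0233). Sox factors (18 of 19 marked, all but Sox15) had 9 genes in the broadest domains (9.37e-07), Irx factors 4 of 6 (0.000654), clustered histone genes 9 of 57 (0.00996) and forkhead factors 6 of 39 (0.0466). Genes that share a domain were each counted in these tests, so neighbours in a family are not independent. The family tests were not repeated with other merge distances. These families and the genes in this paragraph and the next were chosen after the gene-level values were seen, and the marked counts in the replicates' own lists lay within 2 of these.

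The widest domain of the replicated list held no protein-coding start. It covered the starts of the noncoding C130071C03Rik, Gm26803 and Gm33366 and of Mir9-2, a neural microRNA gene, over 29.4 kb (chromosome 13, 83713498 to 83742909), the widest of 20613 domains, with 29.7 and 29.4 kb in the replicates. The domains with Mir9-3 (15.8 kb), Mir124a-2 (15.5 kb) and Mir9-1 (14.1 kb), which also hold other noncoding starts, ranked 11, 12 and 21 by width, and those with Mir124a-1 (8.72 kb) and Mir124a-3 (4.90 kb) ranked 97 and 748. A domain of 16.8 kb over Lncppara (chromosome 15, 85666428 to 85683238) held no annotated start. Of the 8442 CpG-rich protein-coding genes 73 were unmarked. The largest class was 24 predicted or unnamed genes, 8 of them on chromosome 9 between 3000922 and 3038316 bp. The 73 also took in 6 of the 13 CpG-rich genes of Hox groups 9 to 13 and none of the other Hox genes, 8 clustered histone genes, 5 alpha protocadherins, and the germline genes Ddx4, Mael, Sycp1 and Taf7l. In both replicates' own lists 4 of the 73 were marked, Hoxa10 and Hoxc9 among them. Some of the 73 may be copies of each other, such as Entpd4 and Entpd4b with the same CpG ratio (0.65048). Whether reads could be placed uniquely at such genes was not tested, so a missing peak there does not show a missing mark.

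Of the tests in the next paragraphs, those of strong peaks found in 1 replicate only, of CpG content at Hox groups 9 to 13, and of the regional contrast in the pooled list and with merging up to 3000 bp were chosen after the result was seen. Hindbrain and cerebellar genes together had wider domains than telencephalic genes, with medians of 7353 bp over 35 genes and 2760 bp over 18 (permutation p 2e-05, the smallest possible), and 7018 against 2844 bp and 7543 against 2492 bp in the replicates. The contrast kept its side in the pooled list (7353 against 3358 bp, permutation p 1e-04) and with merging up to 3000 bp (8744 against 4109 bp, 0.00246). CpG-rich sequence round the outermost start was argued against. The log2 difference was 1.41 before and 1.39 after a fit on island bases within 10 kb of that start (permutation p 1e-04). A gene's widest domain can lie at another start, where island bases were not counted, so the fit does not speak for sequence there. Merging of peaks and shared domains were argued against too, with permutation p 6.0e-05 with only touching peaks merged and 2.0e-05, the smallest possible, with each domain counted once. As a hypothesis, domain width may follow the regional identity of the tissue, which no other region was here to test.

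Low marked shares were set against CpG-poor starts. At percentiles 9.53, 4.79 and 3.22 of CpG-matched lists, the microglial, liver and muscle shares lay low but were not set apart from lists of like CpG content. With 12, 12 and 13 genes the ranking could miss a further difference. It does not show that CpG content is the whole source. At percentile 0, the pluripotency and germline share lies below what CpG-poor starts allow. The Hox 9 to 13 share also stood at percentile 0. Its starts are mostly CpG-rich, with a median ratio of 0.689 and 81.25% of genes at 0.6 or more, so CpG-poor starts were no candidate there. What keeps those genes unmarked was not tested, and Hox groups 9 to 13 had 10 of 16 genes marked in each replicate's own list.

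Of the 247 genes marked in 1 replicate only, 15 (6.07%, Wilson interval 3.71 to 9.78) had a start peak of −log10 q of at least 10. The other 232 had weaker start peaks, with a median −log10 q of 3.28, against 199 in replicate 1 for genes marked in both. Most of these genes thus rested on weak peaks. Whether weak peaks near the calling threshold are the whole source cannot be told apart, since the interval spans the 5% limit set beforehand. Of those 15 genes, 14 (93.3%, 70.2 to 98.8) had a peak of the other replicate within 2500 bp of a start. Of all peaks that strong, 17557 of 17569 in replicate 1 and 17463 of 17471 in replicate 2 overlapped a peak of the other replicate. Such a partner was thus very likely beforehand. The count therefore cannot decide whether peak edges that cross the limit of the start window are the source. Of the 232 genes with weaker start peaks, 35 (15.1%) had a peak of the other replicate within 2500 bp of a start.

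The 4 peaks at Y-linked genes ranked higher in replicate 2 than in replicate 1. Among 22342 paired peaks, Uty moved from percentile 32.3 to 46.7, Ddx3y from 31.4 to 44.6, Kdm5d from 36.6 to 44.3 and Eif2s3y from 34.2 to 39.9. Against paired peaks of like strength the changes of Uty and Ddx3y stood at percentiles 99.9 and 99.7, that of Kdm5d (7.68 points) at the upper edge of their middle 95% (7.67) and that of Eif2s3y inside it, at percentile 93.0. A larger share of males in the replicate 2 pool may account for this, and predicts a lower rank at the X-linked Xist, which is transcribed in females. The Xist peak moved from percentile 47.3 to 32.8, a change at percentile 0.0455 of 2197 peaks of like strength, which fell on the predicted side. The labels give both pools as mixed, without the number of each sex, so the shares were not measured.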
